A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

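The series holds MNase-seq libraries of budding yeast (Saccharomyces cerevisiae). MNase is a nuclease that cuts DNA between nucleosomes, so that the DNA left over maps where nucleosomes sat. There were 8 libraries, 1 for each of 6 strains with a substitution in histone H3 or H4 and 1 for each of 2 wild types, called H3WT and H4WT here. Per the labels' protocols, cells were grown in rich medium, fixed with formaldehyde, turned into spheroplasts and digested with MNase, mononucleosomal DNA was cut out of a gel, and its ends were sequenced as single reads.

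The deposited files are lists of aligned reads, with 1 line per read giving a chromosome, a start, an end and a strand. In the authors' files every interval was 150 bp long. This was taken to mean that the reads had been extended from their 5' ends, which was not tested. All offsets and midpoints below rest on it. The values are positions, not counts, and carry no normalization. The aligner, its filters and the genome build were not given in the sources used here. On 5 chromosomes the last gene of the R64 gene table ended past the last read. The files may follow another build, or their reads may stop short of the chromosome ends, and which of these holds was not tested. R64 was therefore not taken as the build, and no coordinate of that table was used. All positions below are in the files' own coordinates, counted from 1. Sequence and gene annotation in that build were not used here, so no position was tied to a gene, and base composition was not checked.

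The read 5' end was taken as the interval's start on the plus strand and its end on the minus strand. Each library's strand offset was the lag between 40 and 200 bp with the highest covariance of plus-strand and minus-strand 5' ends, with counts capped at 10 per position and the curve smoothed over 21 bp. A read's nucleosome midpoint was placed at its library's own offset divided by 2. The plan written before the data were examined named a fixed 73 bp as the setting to start from and each library's own offset as the alternative. The offsets turned out far from what 73 bp implies, so the own offset was used for the reported values, and the fixed 73 bp is given with the alternatives. This change was made after the offsets were seen.

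The planned promoter and gene windows need gene positions. The fallback fixed before the data were examined was used in their place. Every library was thinned at random to the lowest total. Nucleosome-depleted regions were called on the 8 thinned libraries pooled, as stretches of 80 to 1000 bp under 0.4 of the chromosome's mean midpoint density, smoothed over 75 bp. Stretches holding 50 bp without any read were dropped as unmapped. The upper length and the rule for unmapped stretches were set after the data were seen. Nucleosome centres were peaks of the pooled density, smoothed with a Gaussian of SD 20 bp and at least 120 bp apart. Positions 451000 to 490500 of chromosome 12, a block of repeats with a pile of reads, were left out of these calls. The share of this block was counted from 459000 to 461000, where its reads lay. This gave 10975 depleted regions with a median length of 133 bp and 56022 nucleosomes.

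For each library the depletion was the midpoint density inside the depleted regions as a percentage of that in the 500 bp on each side. Arrays were aligned on the first nucleosome beside a depleted region, called on both wild types pooled, where no other depleted region lay within 900 bp. The spacing was the slope of 5 successive peak positions, and the amplitude the log2 of the mean of 4 peaks over the mean of 4 troughs. Fuzziness was the median over nucleosomes of the SD of midpoints within 70 bp of the centre, with at least 20 midpoints in both libraries. A nucleosome counted as shifted when its mean midpoint differed by over 20 bp. A depleted region or nucleosome counted as changed when its midpoints differed over 2-fold, with a pseudocount of 0.5, among depleted regions with at least 20 and nucleosomes with at least 50 midpoints in the sum of both libraries. Nucleosomes stand here for the planned gene bodies. The regions named were the 10 with the largest rise and the 10 with the largest fall per mutant. They were ranked by the smaller of the log2 ratios to H3WT and to H4WT with the same sign in both, among regions with at least 50 midpoints in mutant plus own wild type and a log2 ratio between the wild types of at most 1 in size. Distance to a chromosome end, under 20 kb, replaced the planned gene lists, none of which was run.

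Read density along chromosomes was compared in bins of 2 kb, leaving out bins under 0.25 or over 5 times the median wild-type count. A segment was a run of at least 40 kb where the running median of 9 bins lay over 0.3 (log2) from the chromosome's median. Each ratio was centred on the median bin.

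H3 mutants were set against H3WT and H4V86A against H4WT. With 1 library per genotype there is no spread between cultures, so no genotype was tested against another and no p-value is given for one. The only tests across libraries are exact permutation tests of 6 measures against the strand offset over all 8. H3WT against H4WT is the only view of how far libraries differ without a substitution. Intervals are 95% exact binomial for shares, and otherwise from counts or from 4 random splits of the reads into 2 parts. They cover counting error only, since reads without molecular identifiers are not independent molecules, and 25.3 to 32.6% of the reads per library had a distinct start and strand. Totals were 13489460 to 22559472 reads per library, and the thinned depth was 13229598 to 13235231 midpoints.

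The alternatives listed before the data were examined were the other wild type as control, each start and strand once, other windows and minima, a scaling by the median of ratios, all reads, and the exchange of the H3K56Q and H3K56R labels. Alternatives added after seeing the data were the widened depleted regions, the counts without the gained regions of H3K56A, those for the spacing, those for the named regions, and the shares of mitochondrial, repeat and chromosome-end reads against the other wild type. Counting each start and strand once caps every position, so it also shrinks true ratios where reads are dense. In H3WT it raised the density in depleted regions from 11.7 to 27.8% of that in the flanks. A fall under this setting is therefore not by itself a sign of repeated reads. The calls of changed depleted regions and of moved nucleosomes were tested on simulated libraries drawn from H3WT. The regions to be changed were drawn only from those with at least 40 midpoints in H3WT. Of 100 raised 4-fold and 100 lowered 4-fold, all were called, against 260 (3.43%) of 7579 unchanged ones with enough midpoints. How many would be called at regions with fewer midpoints was not tested. The nucleosomes to be moved had at least 50 midpoints in H3WT and lay over 160 bp from the one before. Of 200 moved by 40 bp, 95.5% were called, against 0.0458% of 54595 unmoved ones. Spacings of 160, 165 and 170 bp were recovered as set from plain cosine waves that held no reads. This checks the arithmetic only and says nothing on the error of the spacing in a library. Segments of 1.5-fold over 100 kb were set into chromosomes of 400 random bins, each drawn independently with an SD of 0.3, not into libraries. They were found with both edges within 10 kb in 39 of 50 chromosomes, and 0 were found in chromosomes without one. The SD over all bins of H3K56A was 0.38. Differences that neighbouring bins share were not simulated, so the 0 does not bound false segments in real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.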

Results

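Nucleosome maps were made from 8 yeast strains by sequencing the DNA that MNase left uncut. The labels name 5 substitutions in histone H3 (H3K56A, H3K56Q, H3K56R, H3L61A and H3V46A), 1 in histone H4 (H4V86A), and a wild type for each histone. Lysine 56 of H3 lies near the point where DNA enters and leaves the nucleosome and can be acetylated. Glutamine in its place is often used as a mimic of the acetylated form and arginine as a mimic of the unmodified form. The design implies the question of how each substitution changes where nucleosomes sit. Each genotype had 1 library, so no difference below has a replicate check, and the difference between H3WT and H4WT is the only yardstick. H3K56A had 14596406 reads, H3K56Q 21350083, H3K56R 19148067, H3L61A 13489460, H3V46A 20587407, H3WT 21973866, H4V86A 22559472 and H4WT 19288900. The labels of the H3K56Q and H3K56R libraries and the names of their files are exchanged against each other. The labels were followed, and "H3K56Q" and "H3K56R" below mean the libraries labelled so. The histone loci could not be used to check the labels, because gene positions in the files' build were not used here.

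The libraries differed in strand offset, the distance at which plus-strand and minus-strand read starts covaried most. It was 118 bp in H3K56A, 90 bp in H3WT, 81 bp in H3V46A, 79 bp in H3K56R, 78 bp in H4WT, 75 bp in H4V86A, 73 bp in H3L61A and 65 bp in H3K56Q. The wild types therefore differed by 12 bp.

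**Figure D1:**
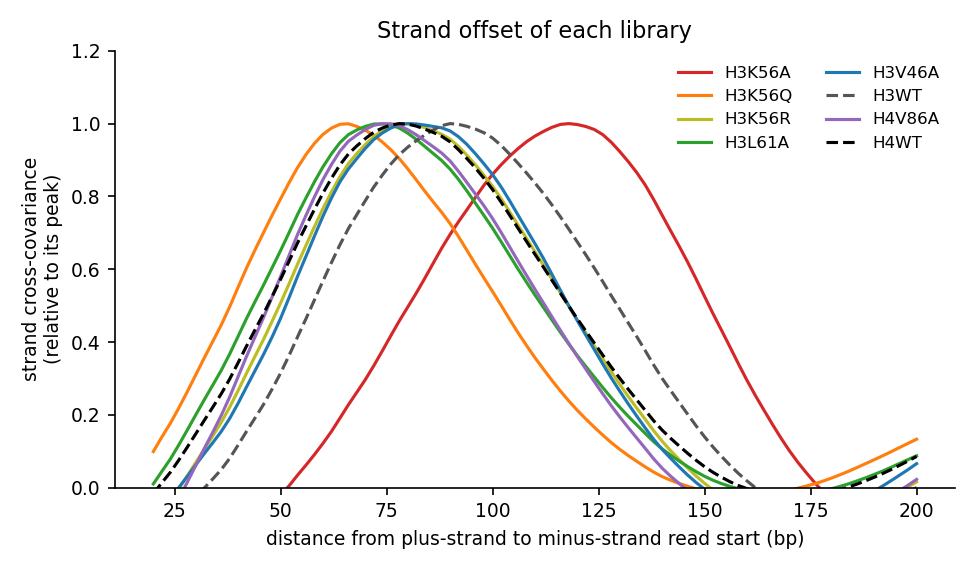
Covariance of plus-strand and minus-strand read starts (vertical axis, relative to each library's peak) against their distance in bp (horizontal axis), 1 line per library, wild types dashed. The peak lies at 118 bp in H3K56A and at 65 bp in H3K56Q, with the wild types at 90 and 78 bp.

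Whole chromosomes and long segments had extra reads in H3K56A and H3V46A. In H3K56A, chromosome 11 had 1.46 times the read density of H3WT over its whole length (median log2 0.55 over 332 bins of 2 kb, interquartile range 0.34 to 0.69), while the medians of the other 15 chromosomes lay between -0.07 and 0.07. A segment of chromosome 12, from position 656001 to 822000, was 3.41-fold higher in H3K56A (median log2 1.77, interquartile range 1.52 to 1.90, 82 bins). A segment of chromosome 14, from position 522001 to 604000, was 1.36-fold higher (median log2 0.45, interquartile range 0.29 to 0.68, 38 bins), and 1.47-fold higher than the rest of that chromosome. In H3V46A all of chromosome 14 was 1.19-fold higher than in H3WT (median log2 0.25, interquartile range 0.11 to 0.38), with the other chromosomes between -0.07 and 0.01. Between the wild types the chromosome medians ran from -0.02 to 0.03. With each start and strand counted once the medians fell to 0.28 for chromosome 11, 0.86 and 0.23 for the 2 segments in H3K56A and 0.11 for chromosome 14 in H3V46A. Some fall is built into that setting, since it counts dense positions only once.

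Smaller departures were seen for chromosome 1 in H3K56R (median log2 0.18, interquartile range 0.05 to 0.32) and chromosome 14 in H4V86A (0.08, interquartile range -0.02 to 0.20). That of H4V86A did not stand apart. Medians of about that size but below 0 were found for chromosome 14 in H3K56R (-0.08) and H3K56A (-0.07) and for chromosome 1 in H3K56Q (-0.07). With each chromosome cut into 4 equal parts, chromosome 1 in H3K56R ran from 0.09 to 0.33, so this departure was not even along the chromosome. The parts of chromosome 11 in H3K56A lay between 0.52 and 0.58, and those of chromosome 14 in H3V46A between 0.21 and 0.29. In the chromosome 12 segment the other 5 mutants lay between -0.01 and 0.07, and in the chromosome 14 segment between -0.04 (H3L61A) and 0.24 (H3V46A), with H4V86A at 0.10 and the wild types 0.06 apart. The left edges of both H3K56A segments lay beside stretches almost without reads, 5000 bp of the surrounding 10 kb on chromosome 12 and 4000 bp on chromosome 14, while the right edges had 0 and 400 bp. Of all windows of 200 bp, 9.45% had at least 1000 bp of such stretches within 5 kb. No segment passed the rule in any other library.

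**Figure D2:**
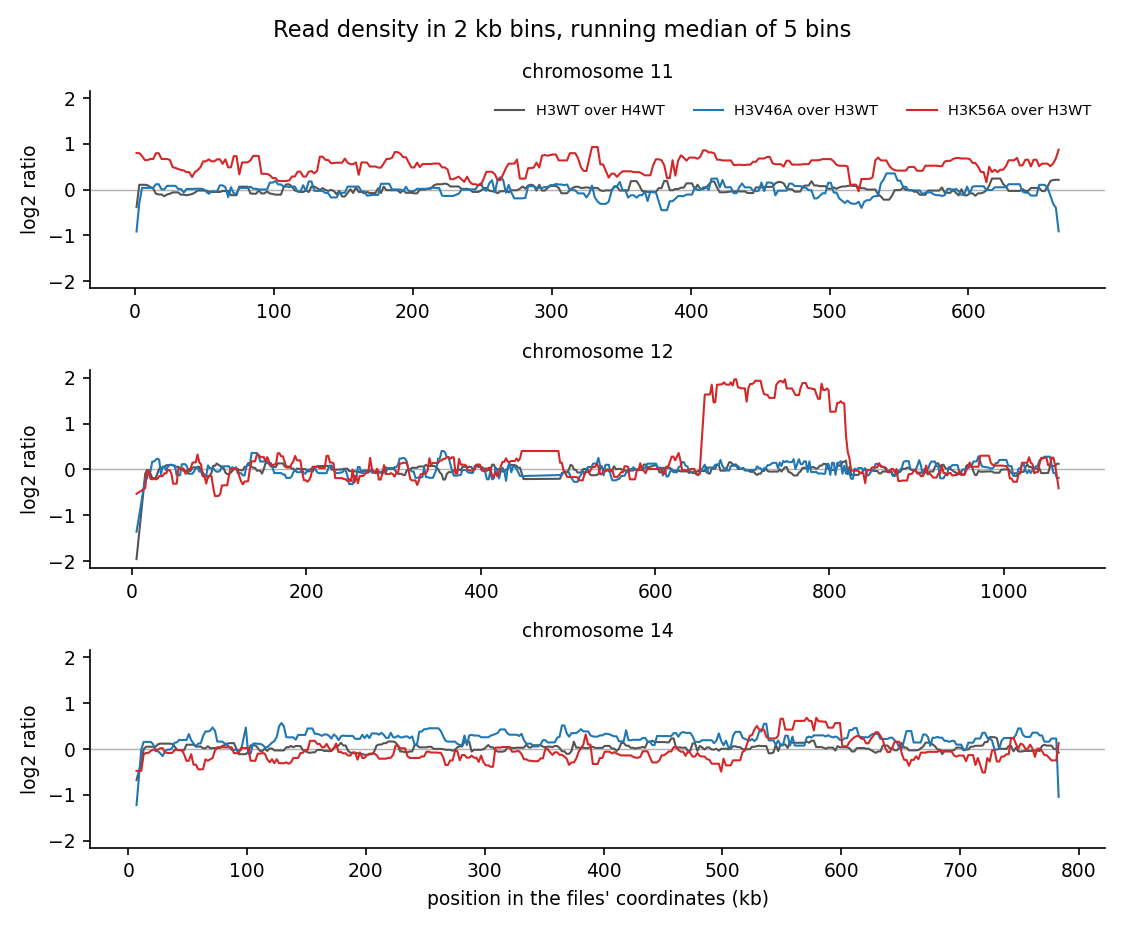
Log2 ratio of read density in 2 kb bins (running median of 5 bins, vertical axis) along chromosomes 11, 12 and 14 (horizontal axis, kb) for H3K56A and H3V46A over H3WT and for H3WT over H4WT. H3K56A is raised over chromosome 11 (median 0.55) and over 656 to 822 kb of chromosome 12 (median 1.77), and H3V46A over chromosome 14 (median 0.25).

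Reads from mitochondrial DNA, which carries no nucleosomes, took 0.965% of all reads in H3K56A (interval 0.960 to 0.970%), 12.9 times the 0.0748% in H3WT (0.0737 to 0.0760%). H4V86A had 0.502%, 3.55 times the 0.142% of H4WT. Against the other wild type the ratios were 6.82 for H3K56A and 6.71 for H4V86A. The shares were 0.319% in H3L61A, 0.207% in H3K56Q, 0.117% in H3V46A and 0.113% in H3K56R. The last 2 lay between the wild types, which themselves differed 0.529-fold. Between 20.5 and 36.7% of the mitochondrial reads of a library lay at 10 positions.

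The outermost 1 kb of the chromosomes, which holds telomere and subtelomere repeats, took 2.31% of the nuclear reads in H3L61A, 4.41 times the 0.524% of H3WT, and 1.40% in H3K56Q, 2.68 times H3WT. Against H4WT the ratios were 2.17 and 1.32. These excesses were not general, since H3L61A was lower than H3WT at 10 and H3K56Q at 11 of the 30 ends with reads. The highest 3 ends held 58.7 and 58.2% of the reads there, against 42.4% in H3WT. H3V46A had 0.223% and H3K56A 0.372%, or 0.426 and 0.709 times H3WT. H3V46A was lower than H3WT at 28 of the 30 ends, whereas H3K56A was lower at 20 and higher at 10. H3K56R had 0.713%, and H4V86A 0.595% against 1.06% in H4WT. The wild types differed 0.492-fold, so H3L61A and H3K56Q were above and H3V46A and H3K56A below both, whereas H3K56R and H4V86A lay between them. From 5 to 20 kb inward the shares were closer, from 2.59% in H3V46A to 3.27% in H3L61A. Reads in this outermost part belong to repeats and their placement is uncertain.

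The repeat block of chromosome 12, where the reads of a high-copy repeat piled up, took 1.07% of the nuclear reads in H3K56Q and 1.54% in H3L61A, against 2.23% in H3WT and 2.14% in H4WT. The share was 3.39% in H3K56A, 2.56% in H3V46A, 2.51% in H4V86A and 2.39% in H3K56R. The wild types differed here by a log2 of 0.06, while H3K56Q differed from H3WT by -1.05, H3L61A by -0.53 and H3K56A by 0.60.

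Nucleosome-depleted regions, which in yeast mostly mark promoters and other regulatory DNA, were less empty in H3K56A, H3V46A and H4V86A than in either wild type. Their midpoint density was 18.2% of that of the flanking DNA in H3K56A (interval 18.1 to 18.3%), 17.4% in H3V46A (17.4 to 17.5%) and 15.0% in H4V86A (15.0 to 15.1%), against 11.7% in H3WT (11.7 to 11.8%) and 8.53% in H4WT (8.49 to 8.57%). H3K56R at 9.40% and H3L61A at 10.6% lay between the wild types, and H3K56Q at 12.6% was just above H3WT.

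Relative to the own wild type the log2 ratio was 0.63 for H3K56A, 0.57 for H3V46A, 0.82 for H4V86A, 0.11 for H3K56Q, -0.15 for H3L61A and -0.32 for H3K56R, each with a counting error under 0.01. The wild types differed by 0.46, so only the first 3 exceeded that, and H4V86A no longer did against H3WT (0.36). Against H4WT both H3K56R (0.14) and H3L61A (0.31) turned to a rise. Moving every read start by 73 bp instead gave 0.30 for H3K56A, 0.60 for H3V46A, 0.52 for H4V86A and 0.53 for H3K56Q, and taking each start and strand once gave 0.34, 0.35, 0.56 and 0.060 in the same order. The wild types then differed by 0.12 and 0.37, so that all mutants but H3K56R exceeded them with the fixed 73 bp and only H4V86A with each start once.

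**Figure D3:**
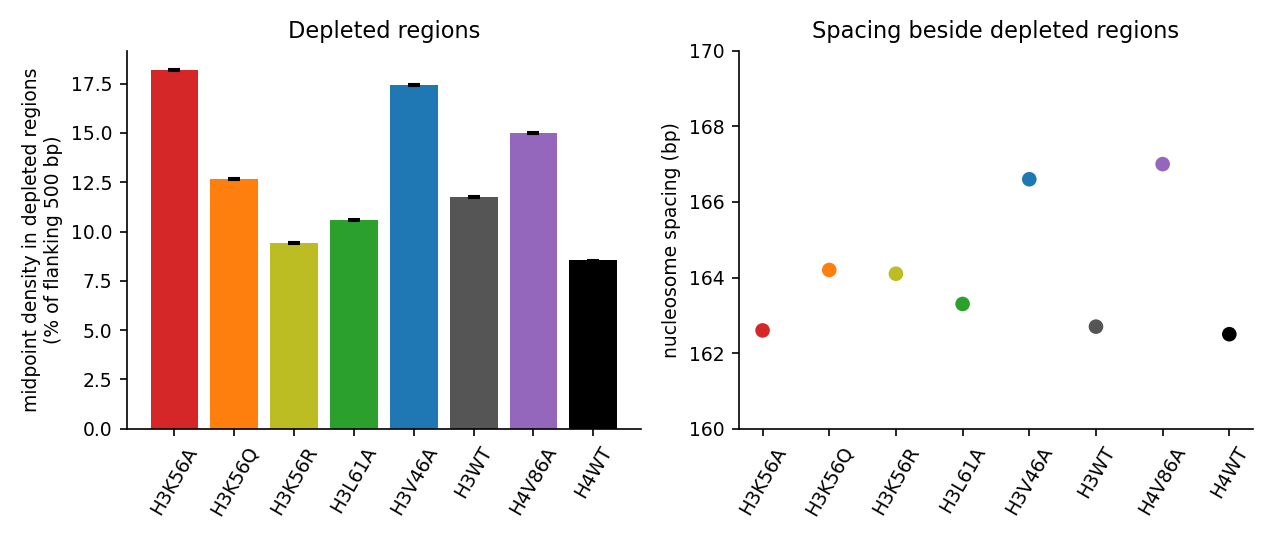
Left, midpoint density inside nucleosome-depleted regions as a percentage of that in the flanking 500 bp, 1 bar per library with its 95% counting interval; right, spacing of nucleosomes beside those regions in bp (axis from 160 to 170 bp). H3K56A, H3V46A and H4V86A stand above both wild types on the left (18.2, 17.4 and 15.0%), and H3V46A and H4V86A on the right (166.6 and 167.0 bp).

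Nucleosomes were spaced wider in H3V46A and H4V86A. Counted outward from the first nucleosome beside a depleted region, over 6992 arrays, the spacing was 166.6 bp in H3V46A and 167.0 bp in H4V86A, against 162.7 bp in H3WT and 162.5 bp in H4WT. The difference to the own wild type was 3.9 bp (counting error 0.259 bp) for H3V46A and 4.5 bp (0.255 bp) for H4V86A, while the wild types differed by 0.2 bp. It was positive on 16 of 16 chromosomes for both, with medians over chromosomes of 3.65 and 4.4 bp. Against the other wild type it was positive on 15 for H3V46A and 16 for H4V86A. The count was also 14 for H3K56Q, 13 for H3K56R and 13 for H3L61A, with smaller medians of 1.15, 1.45 and 0.45 bp. It was 8 for H3K56A and 9 between the wild types. Chromosomes of 1 library are not replicates. H3K56Q (164.2 bp), H3K56R (164.1 bp) and H3L61A (163.3 bp) lay 1.5, 1.4 and 0.6 bp above H3WT, and H3K56A (162.6 bp) lay 0.1 bp below it. With the fixed 73 bp H4V86A (166.1 bp) stayed above all other libraries, whereas H3V46A (163.0 bp) was level with H3K56Q (163.0 bp) and no longer set apart. The wild types then differed by 2.9 bp (160.9 and 158.0 bp), more than the 2.1 bp between H3V46A and H3WT.

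The amplitude of the arrays, the log2 ratio of peaks to troughs, was 0.94 in both wild types. It was lower in H3L61A (0.82), H3V46A (0.82), H3K56Q (0.82) and H4V86A (0.84), close to the wild types in H3K56R (0.95), and higher in H3K56A (0.99). Counting errors of the differences were at most 0.00486. Arrays were aligned on nucleosomes called in the wild types, which may favour the amplitude of these. An alignment on other libraries was not run. With the fixed 73 bp the wild types stood at 0.47 and 0.35, a gap of 0.12. H3K56Q (0.22), H3L61A (0.29) and H3V46A (0.29) then lay below H3WT by more than that gap. H4V86A (0.33) lay below H4WT by less than it. With each start and strand taken once the wild types stood at 0.453 (H3WT) and 0.492 (H4WT), a gap of 0.039. H3K56Q (0.416) and H3V46A (0.404) then lay below H3WT, and H4V86A (0.448) below H4WT, by amounts close to that gap. The difference of H3L61A changed sign with each start and strand taken once, and that of H3K56R with the fixed 73 bp.

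**Figure D4:**
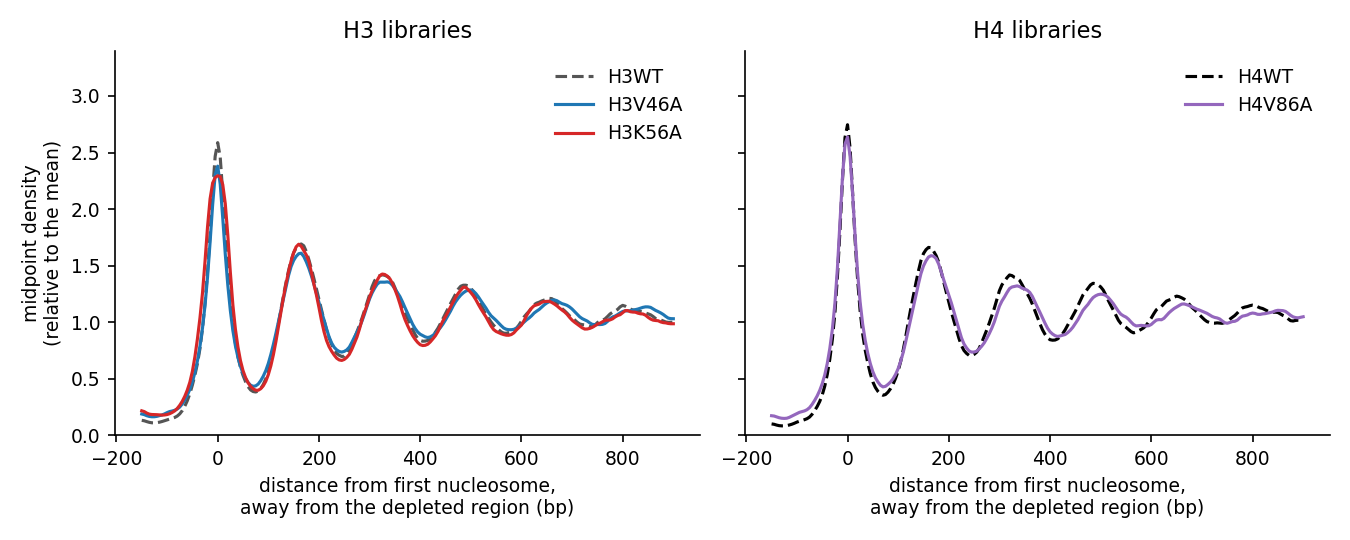
Mean midpoint density (vertical axis, relative to the profile's mean) against the distance in bp from the first nucleosome beside a depleted region (horizontal axis), for 3 H3 libraries and both H4 libraries, wild types dashed. The peaks of H3V46A and H4V86A fall behind those of the wild types with distance, at a spacing of 166.6 and 167.0 bp against 162.7 and 162.5 bp.

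Single nucleosomes moved most often in H3K56A. There, 1964 of 55797 nucleosomes (3.52%, interval 3.37 to 3.68%) had a mean position over 20 bp from that in H3WT. The shares were 1.34% in H4V86A, 1.21% in H3K56R, 1.17% in H3K56Q, 1.07% in H3V46A and 0.978% in H3L61A. Between the wild types 337 of 55686 (0.605%, interval 0.542 to 0.673%) did so. Against H4WT the shares of H3K56Q, H3K56R and H3L61A were 0.369, 0.40 and 0.197%, below the share between the wild types. With each start and strand taken once the share in H3K56A was 1.14%, and at most 0.426% in the other mutants.

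Fuzziness, the SD of the midpoints of a nucleosome, differed between the wild types by more than between 5 of the 6 mutants and their controls. The wild types differed by 1.42 bp (29.0 bp in H3WT, 27.6 bp in H4WT). The differences to the own wild type were 1.00 bp in H4V86A, 0.60 bp in H3V46A, 0.19 bp in H3K56A, -0.46 bp in H3K56Q and -0.74 bp in H3L61A, all smaller than that, and -1.45 bp in H3K56R, whose 27.5 bp was close to H4WT. With the fixed 73 bp this no longer held, as H3K56Q (39.1 bp) lay above and H3K56A (31.8 bp) below both wild types (34.7 and 36.7 bp) by more than the gap between these.

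Changes at single depleted regions were mostly rises in H3K56A, H3V46A and H4V86A. Of 8943 depleted regions with enough midpoints, 2917 were over 2-fold higher and 305 over 2-fold lower in H3K56A than in H3WT. In H3V46A 2186 were higher and 115 lower of 8864, and in H4V86A 3281 were higher and 75 lower of 7963. H3K56R (418 higher, 1483 lower) and H3L61A (525 higher, 1095 lower) had more falls against H3WT, and H3K56Q had 995 higher and 682 lower. Against H4WT the falls gave way to rises, with 638 higher and 256 lower in H3K56R and 713 and 96 in H3L61A. H3K56Q then had 1790 and 62. Between the wild types 1682 of 7419 were higher and 138 lower in H3WT, so the total of 1820 exceeded that of H3K56Q (1677) and H3L61A (1620). In unchanged simulated libraries 3.43% of regions were called, against 24.5% between the wild types. With each start and strand taken once 1450 regions changed in H3K56A, 900 in H3V46A and 1717 in H4V86A.

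The direction of these counts followed the general level of the depleted regions. Their median log2 ratio was 0.60 in H3K56A, 0.56 in H3V46A, 0.84 in H4V86A, 0.11 in H3K56Q, -0.20 in H3L61A, -0.31 in H3K56R and 0.48 between the wild types. Relative to that median, 1349 regions were higher and 1047 lower in H3K56A, 588 and 567 in H3V46A, 966 and 705 in H4V86A, 799 and 850 in H3K56Q, 781 and 836 in H3K56R, and 801 and 733 in H3L61A. Between the wild types they were 627 and 576.

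The largest rise in H3K56A was at position 594808 to 594887 of chromosome 7, with 53 midpoints against 1 in each wild type, so its fold is poorly bounded (log2 5.16, interval 2.82 to 7.50, but 1.34 with the fixed 73 bp and 2.94 with each start and strand once). Of the 10 largest rises, 6 lay in the gained segment of chromosome 12, such as 783628 to 783900 with 370 midpoints against 12 in H3WT and 23 in H4WT. Outside it, 248638 to 248797 of chromosome 9 had 176 against 12 and 10, and 231773 to 231986 of chromosome 15 had 155 against 12 and 9. The largest fall was at 68784 to 68881 of chromosome 3, with 11 midpoints against 66 in H3WT and 44 in H4WT.

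In H3V46A the largest rises were at 628647 to 628978 of chromosome 14 (107 midpoints, 16 in H3WT and 14 in H4WT) and 546169 to 546377 of chromosome 7 (72, 13 and 7). The log2 ratio of the region on chromosome 14 was 2.70, and 1.37 with each start and strand once. The largest fall of H3V46A was at 1049543 to 1049640 of chromosome 4, with 11 against 41 and 25. In H4V86A the largest rise was at 227292 to 227468 of chromosome 1, 3 kb from its end, with 86 midpoints against 3 in H4WT and 6 in H3WT, and the next at 104586 to 104677 of chromosome 2, with 83 against 6 and 7. Their log2 ratios of 4.63 and 3.68 fell to 1.80 and 1.97 with the fixed 73 bp and to 1.66 and 1.34 with each start and strand once. Its largest fall was at 914857 to 915184 of chromosome 4, with 15 against 44 and 39.

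In H3K56R the largest rises were at 214793 to 215268 of chromosome 16 (179 midpoints, 14 in H3WT and 25 in H4WT) and 355027 to 355932 of chromosome 11 (360, 63 and 74). Its largest fall was at 527134 to 527442 of chromosome 16, with 8 against 58 and 57. The same region was among the 10 largest falls of H3K56Q (27 midpoints) and H3L61A (20). In H3K56Q the largest rise was at 82028 to 82168 of chromosome 1 (50 midpoints, 8 and 6), and 576770 to 577050 of chromosome 14 had 244 against 53 and 42. In H3L61A the largest rise was at 545077 to 545193 of chromosome 5, with 71 against 11 and 8, but its log2 ratio of 2.64 fell to 0.31 with each start and strand once. The ratio of the region on chromosome 1 in H3K56Q fell from 2.57 to 1.24 in the same way, and that on chromosome 16 in H3K56R from 3.63 to 2.18. The region at 408508 to 408777 of chromosome 2 was among the 10 largest rises of both H3L61A (67) and H3V46A (68), against 13 in each wild type. What genes lie at these positions was not analysed here.

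Occupancy of nucleosomes changed most widely in H3K56A. There 4740 of 55983 nucleosomes were over 2-fold higher and 3976 over 2-fold lower than in H3WT. H4V86A had 2841 higher and 370 lower, H3V46A 1711 and 905, H3K56R 1069 and 1417, H3K56Q 885 and 1261, and H3L61A 743 and 1357. Between the wild types 1301 were higher and 447 lower. Scaled by the median of ratios, 5365 were higher and 3239 lower in H3K56A, and 2627 and 440 in H4V86A. The split was then near even in H3V46A (1328 and 1158) and H3L61A (917 and 1064). It was 1037 and 1466 in H3K56R, 849 and 1305 in H3K56Q, and 1155 and 519 between the wild types. Without chromosome 11 and the gained segments H3K56A still had 7228 changed nucleosomes, but with each start and strand taken once the number was 978. Against H4WT the numbers were 908 in H3K56Q, 881 in H3K56R and 333 in H3L61A, all below the 1748 between the wild types. Most of these were rises (688, 660 and 259). H3K56A (10550) and H3V46A (4405) stayed above the 1748.

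Regions near chromosome ends stood apart little. The 497 depleted regions within 20 kb of an end had a median log2 ratio of 0.69 in H4V86A against 0.84 elsewhere, at percentile 0.165 of 10000 random lists matched on mean midpoints, and of 0.45 in H3K56A against 0.58, at percentile 1.03. For the 2084 nucleosomes there, the medians were -0.17 in H3L61A (elsewhere -0.06), -0.08 in H3K56Q (0.01), -0.02 in H3V46A (0.06) and -0.01 in H4V86A (0.03), each below all 10000 random lists. Between the wild types the percentiles were 14.3 for depleted regions and 7.15 for nucleosomes. The random lists hold scattered members, whereas those near ends adjoin, so the percentiles do not allow for differences that neighbours share. The share of reads from 5 to 20 kb inward went the other way in H3L61A (1.18 times H3WT) and H3K56Q (1.10). It fell in H3V46A (0.931) and H4V86A (0.932 times H4WT).

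The 3 substitutions of H3 lysine 56 did not move together. H3K56A had fuller depleted regions than the other 2 (18.2% against 12.6% in H3K56Q and 9.40% in H3K56R), but with the fixed 73 bp H3K56Q stood higher (23.4% against 20.0% in H3K56A). That setting moved reads farther past the own offset divided by 2 in H3K56Q (32 bp) than in H3K56A (59 bp). H3K56A was alone among the 3 in the gains of chromosome 11 and the segments of chromosomes 12 and 14 and had the highest mitochondrial share, while H3K56R had the smaller rise of chromosome 1. H3K56Q and H3K56R were close in spacing (164.2 and 164.1 bp) and in shifted nucleosomes (1.17 and 1.21%), and differed in the chromosome 12 repeat block (1.07 and 2.39%). Their spacings moved apart to 163.0 and 160.4 bp with the fixed 73 bp, and their shares at the chromosome ends (1.40 and 0.713%) differed 1.97-fold, no more than the 2.03-fold between the wild types. Across nucleosomes, the log2 levels of H3K56Q correlated at Pearson r 0.90 with H3K56R, 0.95 with H3L61A and 0.62 with H3K56A, and those of the wild types at 0.91. With H4WT the r was 0.93 for H3K56Q, 0.93 for H3K56R and 0.96 for H3L61A, and with H3WT 0.87, 0.87 and 0.88. These libraries were thus about as close to H4WT as to each other, so the values show no likeness particular to the mutants.

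Log2 ratios over 8605 depleted regions correlated between H3K56Q and H3K56R at r 0.63 (Spearman rho 0.62), between H3K56A and H3K56R at 0.40 (rho 0.38) and between H3K56A and H3K56Q at 0.31 (rho 0.28), all against H3WT. Simulated unchanged libraries sharing a control gave 0.50. The simulation gave the control and both libraries the same spread, so an r near 0.50 was built in. The covariances were 0.46, 0.33 and 0.24, against 0.30 in the simulation. That value rests on splitting the difference between the wild types evenly over both. A larger share in H3WT would raise it, so the 0.46 cannot be read as a change common to both mutants. When the libraries of a pair were set against different wild types, r for H3K56Q and H3K56R was 0.07 or 0.09, for H3K56A and H3K56R -0.09 or 0.18, and for H3K56A and H3K56Q -0.18 or 0.06. H3V46A and H4V86A, which share no control, had r -0.02 (rho -0.03). These correlations are across regions, which are not independent replicates.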

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

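All tests in this part were chosen after the result was seen. With 1 library per genotype the search for outlying samples had no group to work on. Windows of 200 bp that lay outside every called depleted region and nucleosome and the outermost 1 kb, and that stood over 1.5 (log2) above all other libraries, were looked at, since no comparison but that of the 2 kb bins used them. Values are scaled to 20000000 nuclear reads. H3V46A had 3 such windows, with 284.0 at 268001 to 268200 of chromosome 13 (292 reads, wild types 12.8 and 3.1), 100.2 at 355601 to 355800 of chromosome 9 (103 reads, wild types 5.5 and 1.0) and 49.6 at 238201 to 238400 of chromosome 2 (51 reads, wild types 8.2 and 5.2). Distinct starts made up 16.1, 32.0 and 58.8% of these reads.

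The density in depleted regions of H3K56A, H3V46A and H4V86A was weighed against 2 technical explanations, and the tables exclude neither. For the degree of digestion, read from the strand offset, H3V46A exceeded every library outside the 3 with an offset within 3 bp by at least 1.86-fold, but with the fixed 73 bp by 1.49-fold, under the 1.5 set as bound, and H4V86A by 1.42 and 1.18-fold, while no library had an offset near that of H3K56A. For evenly spread background reads, the share that would fill the regions (7.43% for H3K56A, 6.56% for H3V46A, 7.09% for H4V86A) predicts a fall of array amplitude by 0.05 to 0.06, and the observed changes were -84.3, 222 and 174% of it. The amplitudes of H3K56Q, H3K56R and H3L61A differed from H3WT by -0.12 to 0.01, a range wider than that fall, so background and a change of the nucleosomes cannot be told apart. The substitutions themselves stay open and untested, since each genotype is 1 library.

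The wider spacing of H3V46A and H4V86A was weighed against 2 as well. With each start and strand taken once the smaller of the 2 differences was 3.2 bp, against 0.6 bp between the wild types, which argues against reads repeated at a few positions. Digestion, read from the offset, stays open for both: in the reported setting they exceeded the highest of the other 6 libraries by 2.4 and 2.8 bp, more than the range of those 6 (1.7 bp), but with the fixed 73 bp, where that range was 5.4 bp, H3V46A exceeded the highest by 0 bp (0%) and H4V86A by 3.1 bp (57.4% of the range). That the substitutions of these valines may loosen the packing of arrays is a hypothesis that 1 library per genotype leaves untested.

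The gains in H3K56A were weighed against 2 more. With each start and strand taken once, chromosome 11 and the segments of chromosomes 12 and 14 exceeded the highest of all stretches of as many bins elsewhere by 0.27, 0.80 and 0.081 (log2, errors 0.02, 0.04 and 0.05), which argues against piles of reads at a few positions. With chromosomes cut into 4 equal parts, the lowest part of chromosome 11 exceeded the highest part of every other chromosome, the 2 segments left out, by 0.24 (0.52 and 0.28). The gain thus held over all of chromosome 11. This cannot decide on a trend of digestion or base composition, since chromosome 11 was picked for its high median and base composition was not measured. For the segments a trend was not tested. Extra copies of chromosome 11 and of the 2 segments in part or all of the cells may account for the gains. Whether these came from the substitution or arose by chance in the culture was not tested.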

How the results depend on the processing

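The measures of depleted regions, arrays and nucleosomes and the similarities were run again with other settings, and the cause of the moves was not tested. The shares of mitochondrial, repeat and chromosome-end reads were run against the other wild type only, and the random lists were not run again. Except for similarities and named regions, all values that moved beyond the counting error (for counts, beyond 1.5-fold) are listed, in the order H3K56A, H3K56Q, H3K56R, H3L61A, H3V46A and H4V86A unless libraries are named. Depletion, amplitude and fuzziness are differences to the wild type (log2, log2 and bp), spacing is in bp, shifts are percentages, and changes are counts over 2-fold. Taking the other wild type gave for depletion 1.09, 0.57, 0.14, 0.31, 1.03 and 0.36, for fuzziness 1.62, 0.96, -0.022, 0.68, 2.02 and -0.43, for shifts 4.72, 0.369, 0.40, 0.197, 1.51 and 1.79, and for spacing 0.1 in H3K56A and 0.8 in H3L61A. The log2 ratios of read shares were then 2.77, 0.55, -0.33, 1.17, -0.27 and 2.75 for mitochondrial DNA, 0.66, -0.995, 0.16, -0.47, 0.26 and 0.17 for the chromosome 12 repeat block, and -1.52, 0.40, -0.58, 1.12, -2.25 and 0.18 for the outermost 1 kb. It also gave 4844, 894, 809, 4616 and 1880 changed depleted regions for all but H3K56Q, and 908, 881, 333 and 4405 changed nucleosomes for H3K56Q, H3K56R, H3L61A and H3V46A. Keeping each start and strand once gave for depletion 0.34, 0.060, -0.28, -0.29, 0.35 and 0.56, for amplitude 0.10, -0.037, 0.043, 0.014, -0.050 and -0.044, and for shifts 1.14, 0.383, 0.426, 0.337, 0.35 and 0.384. Fuzziness then was -0.43, -1.29, -1.39, 0.38 and 0.91 for all but H3K56Q, and spacing 1.1, -0.2, 3.2 and 3.9 for H3K56R, H3L61A, H3V46A and H4V86A. Changed depleted regions fell to 1450, 812, 1018, 992, 900 and 1717 and changed nucleosomes to 978, 111, 155, 206, 119 and 294. With the fixed 73 bp of the plan, depletion was 0.30, 0.53, 0.023, 0.17, 0.60 and 0.52, amplitude 0.35, -0.25, -0.077, -0.18, -0.18 and -0.020, and spacing 1.5, 2.1, -0.5, -3.3, 2.1 and 8.1. Under the same setting fuzziness was -2.93, 4.36, 1.60, 2.45, 2.09 and -0.45, shifts 4.94, 1.34, 1.36, 1.49, 0.724 and 1.15, and H3K56Q had 2848 changed depleted regions. Widening the depleted regions by 25 bp on each side gave 0.57, 0.062, -0.21, -0.16, 0.43 and 0.63. Without regions near chromosome ends depletion was 0.65 in H3K56A and -0.14 in H3L61A. A minimum of 50 midpoints gave a fuzziness of 0.15, -0.40, -1.37, -0.68 and 0.61 in the H3 mutants. Shifts over 30 bp made up 0.421, 0.0735, 0.0807, 0.061, 0.0358 and 0.0968%. With no minimum, 2782, 3283 and 2825 depleted regions changed in H3K56Q, H3K56R and H3L61A, and with the median of ratios 1155 in H3V46A and 1671 in H4V86A. Exchanging the H3K56Q and H3K56R libraries by their file names gave a depletion of -0.32 for H3K56Q and 0.11 for H3K56R, and an r with H3K56A of 0.40 and 0.31. Setting the first library of a pair against H3WT and the second against H4WT gave r of 0.058 for H3K56A with H3K56Q, 0.18 with H3K56R and -0.12 with H3V46A, 0.093 for H3K56Q with H3K56R, and -0.22, -0.27 and -0.29 for H3V46A with H3K56Q, H3K56R and H3L61A. The reverse gave -0.18, -0.095, -0.20 and -0.14 for H3K56A with the other 4 H3 mutants, 0.068 for H3K56Q with H3K56R, and 0.031, 0.10, 0.057 and -0.042 for H4V86A with H3K56Q, H3K56R, H3L61A and H3V46A. Of 38 similarities run again 22 moved and 11 changed sign, and only the changes of sign and the pairs of main interest are listed. The closest pair, H3K56Q and H3L61A, moved from 0.76 to 0.21 and 0.16 with different wild types. Of 240 values of the 120 named regions, run again with each start and strand once and with the fixed 73 bp, 150 stayed within counting error, 84 moved and 6 changed sign, all of them falls. These were in H3K56Q 777154 on chromosome 13 (0.063 with each start once, 0.66 with 73 bp), and with 73 bp 404989 on chromosome 16 (0.18) and 280778 on chromosome 9 (0.048), in H3K56R 430895 on chromosome 11 (0.18) and in H3L61A 544641 on chromosome 7 (0.196). The depletion of H3K56A, H3V46A and H4V86A stayed above the control in every setting, as did the spacing of H3V46A and H4V86A, although with the fixed 73 bp that of H3V46A differed by less than the wild types did (2.9 bp). The signs of depletion in H3K56R and H3L61A, of amplitude in H3L61A and H3K56R, of spacing in H3L61A, H3K56R and H3K56A, of fuzziness in all mutants but H3V46A, of the mitochondrial share in H3K56R and H3V46A and of the chromosome-end share in H3K56R and H4V86A depended on the setting, as did those of most similarities. Not run were the centring by base composition and the window upstream of start codons, which need the genome of the files, and leaving out a replicate, since each group has 1 library. No paired analysis was possible because each genotype has 1 library.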

Other observations

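All tests in this part were chosen after the result was seen. H3K56Q had 0 reads at 255401 to 255600 of chromosome 2, which allows up to 3 reads, where the other 7 libraries had 31 to 149. This window borders a stretch that was empty in the other libraries too. From 255601 to 256200 these held 0 reads and H3K56Q held 2. H3K56Q had 263 reads at 576801 to 577000 of chromosome 14, where the others had 7 to 29. This window lies within the depleted region at 576770 to 577050 that was named above as a rise of H3K56Q. In the R64 gene table the histone gene pairs HHT1-HHF1 and HHT2-HHF2 lie on chromosomes 2 and 14. Whether the windows on these chromosomes fall on them was not tested. In H3L61A the last 13 bp of chromosome 3 held 1754 reads, all on the minus strand with 0.741% distinct starts, against 49 to 918 reads in the others. H4V86A stood above all other libraries at 41801 to 42000 of chromosome 3 (302 reads, of which 298 were on the minus strand, with 14.2% distinct starts, against 17 to 58 reads in the others) and below them at 915001 to 915200 of chromosome 4 (6 reads, 35 to 87 in the others). H3V46A was below all others in 4 adjoining windows from 877601 to 878400 of chromosome 4. By the same rule 528 windows stood above and 28 below all others in H3K56A, and at most 5 above and 11 below in any other library. Of the 528 windows, 297 lay in its 2 gained segments.

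Across the 8 libraries, 6 measures were set against the strand offset. Array amplitude rose with it (Pearson r 0.73, exact permutation p = 0.0098, adjusted p = 0.0588; Spearman rho 0.67, exact permutation p = 0.0831, adjusted p = 0.249), and without H3K56A and H3K56Q, the 2 farthest from the median offset, r was 0.53. The share of reads in the outermost 1 kb fell with it by rank (rho -0.83, exact permutation p = 0.0154, adjusted p = 0.0923; r -0.53, exact permutation p = 0.173, adjusted p = 0.259), and r without the same 2 was -0.58. Neither passed 0.05 after adjustment. Amplitude, depletion, spacing and fuzziness were measured on midpoints placed by the same offset, so part of their relation to it may be built in. For the density in depleted regions r was 0.53 (exact permutation p = 0.172, adjusted p = 0.259; rho 0.36, exact permutation p = 0.389, adjusted p = 0.467) and 0.07 without those 2. For spacing r was -0.38 (exact permutation p = 0.365, adjusted p = 0.365; rho -0.38) and -0.28 without those 2, and for fuzziness 0.43 (exact permutation p = 0.303, adjusted p = 0.364; rho 0.52) and 0.42 without them. For the mitochondrial share r was 0.69 (exact permutation p = 0.108, adjusted p = 0.259; rho -0.21) and turned to -0.69 without the same 2.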
